A study of Danio rerio with 16 samples.

How the data were processed

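The data are FPKM tables of RNA sequencing from dissected eyes and dissected brains of wild-type zebrafish larvae at 120 hpf. The larvae were exposed from 6 hpf to IPP at 0.2 uM, with DMSO at 0.02% as the vehicle, or to the vehicle alone. There are 4 libraries in each of 4 groups and 16 in all. Per the labels, paired reads of 150 bp were sequenced to a nominal 40 M per sample. Per the submitters' processing notes, HISAT2 2.0.5 and featureCounts 1.5.0-p3 were used, and their roles are not stated. The genome build, the annotation and the FPKM formula are not given in the sources used here. The labels describe both a directional and a non-directional library preparation, so the use of strand is unclear. Of the 80 different genes named singly with a test in the text, 19 overlap another annotated gene and 12 overlap one of the opposite strand.

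The authors deposited FPKM values, 1 table per tissue, with gene lengths, symbols, identifiers, coordinates and biotypes. The values were checked as FPKM. FPKM times gene length was a whole multiple of 1 step in 100% of the values of each library, to within 0.01 read, which returns whole reads per gene. These reads summed to 9.62 M to 16.3 M per library. The library totals behind the FPKM differ from these sums, and relative to their geometric mean they equal median-of-ratios size factors within each tissue, so the tables of eye and brain were scaled separately. Each table holds 31901 genes, of which 29178 identifiers were found in the reference gene table (17026 with the same symbol) and 25431 are annotated as protein-coding.

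Genes with a mean of at least 0.5 FPKM over the 8 libraries of a tissue were tested, 17096 in eye and 17533 in brain. IPP was compared with DMSO within each tissue on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend), two-sided, with the Benjamini-Hochberg adjustment and a threshold of 0.05. No covariate and no block was used, since no label pairs the samples. The difference between the tissues was tested as an interaction contrast over the 15856 genes tested in both, and the fold changes of both tissues were correlated across these genes. The labels were read with jsonlite 2.0.0.

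Fixed lists of genes for 47 pathways, cell types and possible sources of foreign RNA were written before the data were examined, with 1633 entries, of which 1561 matched the tables. Each list with at least 5 tested genes was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Beside it stand camera with an estimated correlation, fry, and an exact two-sided permutation test of the mean level of the list over the 70 arrangements of 8 libraries, whose smallest p is 0.0286. Counts adjusted over the list alone apply the adjustment to the genes of that list only.

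Genes were named by a rule that was fixed at the same time. It takes the called genes with the largest changes, or, where fewer than 4 are called in a tissue, the 5 genes per direction with the smallest unadjusted p, given as not passing. These had to have a mean of at least 1 FPKM, an assigned symbol and full separation of the groups, conditions that the rule states for called genes and that were kept for this case. Symbols that begin with LO, NC_, RF or dre-mir were added to the clone-style names that the rule leaves out. The rule adds up to 4 members with the smallest p for each list described, of which the text gives some, and 12 genes to be reported in any case. Genes outside the rule are marked as named after their values were seen, and the marker genes of foreign tissue and of activity given per library are the 3 most abundant of their list.

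The alternatives planned with these choices were pseudocounts of 0.1 and 1, no filter and a filter at 2 FPKM, median-of-ratios scaling, quantile normalization, rescaling of the eye libraries without lens genes, the replicate number as a block, robust eBayes, library quality weights, limma-voom on the rebuilt reads, both other list tests, and leaving out each library in turn. Chosen after seeing the data were protein-coding genes only and leaving out eye DMSO 4 and IPP 4, brain DMSO 1 and IPP 4, or IPP 3 and IPP 4 of both tissues. The levels of the skin list and of the liver and gut list as covariates were also chosen then. So was, for the interaction, the pairing of same-labelled eye and brain libraries, as eye minus brain per label. Each was run with 1 choice changed at a time.

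The test was tried on simulated data with the means and spreads of these libraries. The changed genes were drawn from those with a mean of at least 2 FPKM. Each gene varied on its own, so joint shifts of many genes in a library were not simulated. In eye it found 73 of 100 genes changed by 2-fold and 96 of 100 changed by 4-fold and called 13 of 16856 unchanged genes, and in brain it found 55 and 85 of 100 and called 8 of 17293. Within a group, a library was marked as far from the others by Dixon's criterion at a critical value of 0.829. All 35 distinct splits of the 8 libraries of a tissue into 4 and 4 were tested as well, and 100 drawn splits for the interaction. Raw reads were not analysed here.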

Results

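RNA of dissected eyes and of dissected brains from wild-type zebrafish larvae at 120 hours post fertilization (hpf) was sequenced. The larvae had been kept since 6 hpf in 0.2 uM phenol isopropylated phosphate (IPP), an organophosphate used as a flame retardant and plasticizer, or in the vehicle alone, 0.02% dimethyl sulfoxide (DMSO). The 16 libraries form 4 groups of 4, which are DMSO eyes, IPP eyes, DMSO brains and IPP brains. Expression was given in FPKM, reads scaled by the length of the gene and by a library total. There are 2 tables, 1 per tissue, with 31901 genes in each. The read numbers behind the tables summed to 10.6 M to 12.5 M per eye library and to 9.62 M to 16.3 M per brain library. The series states a nominal 40 M reads per sample. The sums hold only reads assigned to genes, and whether a pair counts as 1 read or 2 is not stated for either number. The numbers are thus not directly comparable. Genes of the mitochondrial genome took 3.94% to 4.41% of the reads of the eye libraries and 4.52% to 5.25% of those of the brain libraries.

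Values below are mean FPKM ± SD over the 4 libraries of a group. Changes are log2 fold changes of IPP over DMSO, computed on FPKM + 0.5, with the standard error (SE) of the fit. Coordinates are those of the tables, whose genome build is not given in the sources used here. The labels do not say whether the libraries of a group come from separate clutches or pools, so the p-values measure only the spread between these libraries. Near-identical family members, such as the globin, green cone opsin and gamma crystallin M2d genes, share reads and their separate values are uncertain.

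The comparison of IPP eyes with DMSO eyes asks what the exposure did to gene expression in the organ that starts the photomotor response, the larval movement set off by light that the study is about. Genes of ganglion, horizontal and amacrine cells lay lower in IPP eyes, while the lists of photoreceptor genes were not called lower. Of 29 measured genes of horizontal and amacrine cells, the interneurons of the retina, 26 lay lower, with a median log2 fold change of -0.27. Of 24 measured genes of retinal ganglion cells, whose axons form the optic nerve, 17 lay lower, with a median of -0.24. Of 30 genes of mature neurons 26 lay lower, with a median of -0.26. These lists were called by limma's camera with a preset correlation between genes and not with an estimated one (adjusted p = 0.584 for each). The other cell types of the inner retina showed no such call with the preset one, and the lists were not tested against each other. Of 20 bipolar cell genes 13 lay lower (median -0.08, adjusted p = 0.262), and of 21 genes of Mueller glia 14 did (median -0.03, adjusted p = 0.779). No single gene passed the correction over all 17096 genes tested, so every gene value below is one that did not pass.

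Among the ganglion cell genes, the transcription factor genes irx4a, isl2b and pou4f1 and the RNA-binding protein gene rbpms2b had the smallest p-values. The gene pou4f1 stood at 19.4 ± 2.43 FPKM in DMSO eyes and 10.7 ± 1.77 in IPP eyes (log2 fold change -0.83, SE 0.14) and rbpms2b changed by -0.66 on the log2 scale (SE 0.12). Among the horizontal and amacrine cell genes, the neuropeptide gene npy stood at 6.2 ± 1.23 and 2.68 ± 0.566 FPKM (-1.07, SE 0.19) and vip, which encodes another neuropeptide, at 44.8 ± 2.97 and 34.4 ± 2.74. The gene rprma, a reprimo gene, changed by -1.02 on the log2 scale and slc18a3a, the vesicular acetylcholine transporter, by -0.50. Among the mature neuron genes, the neuronal enolase gene eno2 stood at 94.6 ± 10 and 63.0 ± 10.1 FPKM, with the splicing regulator rbfox1 at -0.45 and the release machinery gene snap25a at -0.45 on the log2 scale. Adjusted over the list alone, 15 horizontal and amacrine cell genes, 11 ganglion cell genes and 13 mature neuron genes passed, all of them lower, and 0 of these passed over all genes tested. The lists of ganglion cells and mature neurons share 6 genes.

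As sets, these lists passed the competitive test of limma's camera with a preset correlation between genes. The adjusted p was 7.1e-08 for horizontal and amacrine cells, 3.0e-07 for mature neurons and 1.9e-05 for ganglion cells, and leaving out any single library ended none of these calls. With an estimated correlation none of the lists passed (adjusted p = 0.584 with an estimated correlation for each of them). In the horizontal and amacrine cell list the mean level of all 4 IPP libraries lay below that of all 4 DMSO libraries, which gives an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 libraries allow, and 0.269 after adjustment over the 47 lists. In the lists of ganglion cells and mature neurons the groups overlap (exact two-sided permutation p of 0.0571 for each). Relative to the mean of the eye libraries on the log2 scale, DMSO library 4 lay there at -0.0144 and -0.0245 and IPP library 2 at -0.00622 and 0.00226. For horizontal and amacrine cells DMSO library 4 lay at 0.05, against 0.12 to 0.21 for the other DMSO libraries.

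**Figure D1:**
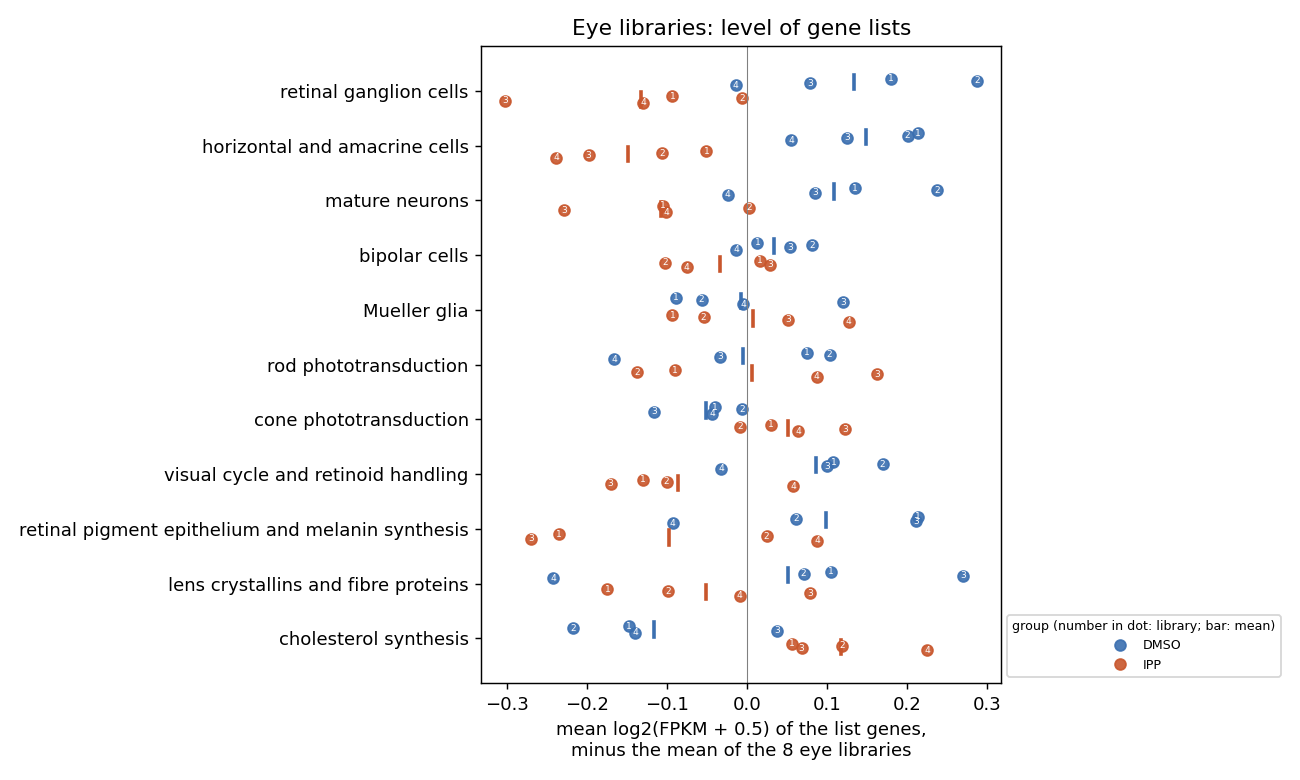
Mean log2(FPKM + 0.5) of the genes of 11 fixed lists in each eye library, minus the mean of the 8 eye libraries, on the x axis, with 1 list per line; dots are libraries with their number, blue for DMSO and orange for IPP, and bars are group means. In the horizontal and amacrine cell list the 4 IPP libraries lie between -0.24 and -0.05 and the DMSO libraries between 0.05 and 0.21, while the groups overlap in the rod phototransduction list.

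Among the lists of neuronal signalling, those of glutamate, acetylcholine and synaptic vesicles were called lower with the preset correlation and lost the call with an estimated one (adjusted p = 0.584, 0.604 and 0.733). The exact two-sided permutation p of their mean levels was 0.114, 0.0857 and 0.743. The list of GABA and glycine, transmitters of amacrine and horizontal cells, was not called. Of 33 GABA and glycine genes 16 lay higher and 17 lower (median -0.00707, adjusted p = 0.43). The GABA and glycine genes went both ways, with 8 lower and 2 higher at an unadjusted p under 0.05, and the list passed fry's test for changes in either direction (adjusted p = 0.0408). Of 26 dopamine and serotonin genes 16 lay lower (median -0.14, adjusted p = 0.0976, and adjusted p = 0.584 with an estimated correlation), a list that passed with quantile normalization (0.034) and without DMSO library 2 (0.0494). Of 36 glutamate signalling genes 24 lay lower (median -0.20). Among them were the NMDA receptor gene grin1a, at 171 ± 17.8 FPKM in DMSO eyes and 113 ± 17.1 in IPP eyes, and the AMPA receptor gene gria4a, at 20.7 ± 3.23 and 13.4 ± 1.66. Of these 36 genes 15 passed when adjusted over the list alone, 14 of them lower. Of 16 acetylcholine signalling genes 14 lay lower (median -0.23), with chata, the choline acetyltransferase, at 10.3 ± 0.802 and 7.86 ± 0.854 FPKM, and slc18a3a alone passed when adjusted over the list alone. The genes chata and slc18a3a also belong to the horizontal and amacrine cell list. Of 37 genes of synaptic vesicles and transmitter release 26 lay lower (median -0.08) and 4 passed over the list alone. Of these, stxbp1a, a partner of the SNARE proteins, stood at 138 ± 23.9 and 90.8 ± 14.8 FPKM and the vesicle protein gene sv2ba lay higher, at 38.4 ± 3.63 and 50.8 ± 5.04. The camera adjusted p with the preset correlation was 0.000335 for glutamate, 0.00564 for acetylcholine and 0.0286 for synaptic vesicles. With the levels of the skin list and of the liver and gut list as covariates, chosen after seeing the data, the acetylcholine call ended (adjusted p = 0.212), as it did without DMSO library 4 and IPP library 4 (0.0639) and without IPP libraries 3 and 4 (0.121). The synaptic vesicle call ended without any 1 of DMSO libraries 1, 2 and 4 and IPP libraries 3 and 4 (adjusted p 0.0671 to 0.13), with quantile normalization (0.172), with the covariates (0.648) and in the same sets of left-out libraries (0.202 and 0.273). Its mean of -0.0284 turned positive with the covariates (0.0192), in these sets (0.0138 and 0.0344), by limma-voom (0.0132) and with a pseudocount of 0.1 (0.000106).

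The lists of photoreceptor genes were not called lower. The rod opsin gene rho stood at 4601 ± 920 FPKM in DMSO eyes and 4394 ± 378 in IPP eyes (log2 fold change -0.05, SE 0.16), the green cone opsin gene opn1mw1 at 2787 ± 75.5 and 2857 ± 711 (0.00), and the red cone opsin gene opn1lw2 at 1277 ± 150 and 1371 ± 362 (0.07). The transducin genes changed by 0.01 (gnat1, rods) and -0.03 (gnat2, cones), and the signs of rho and gnat2 turned with quantile normalization, to 0.06 and 0.04. Of 18 rod phototransduction genes 12 lay lower and 6 higher, with a median of -0.02, a mean of 0.01 and a camera direction of lower (adjusted p = 0.779), which turned to higher with quantile normalization (mean 0.03). Of 27 cone phototransduction genes 18 lay higher (median 0.07, adjusted p = 0.0976), and of 31 genes of photoreceptor development and structure 22 did (median 0.07, adjusted p = 0.0931). Both of these lists passed as higher with quantile normalization (adjusted p = 0.00999 for each), without DMSO library 2 (0.0447 and 0.0371) and with the covariates (0.0379 and 0.00286). The structure list also passed with the filter at 2 FPKM (adjusted p = 0.0391), by limma-voom (0.0456) and without IPP library 4 (0.0278). With an estimated correlation neither passed (adjusted p = 0.612 for each), nor did they by fry (0.237 and 0.367). Among their members were guca1e, a guanylate cyclase activator of cones, at 3.03 ± 0.534 and 4.58 ± 0.221 FPKM, the cone channel gene cnga3b at 24.5 ± 3.49 and 34.1 ± 5.42, and the polarity gene crb2a at 4.51 ± 1.60 and 8.21 ± 1.06.

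Most genes of the pigment epithelium list and of the visual cycle list lay lower in IPP eyes. The cell types in which they changed, rlbp1b included, were not told apart. Of 24 genes of the retinal pigment epithelium and of melanin synthesis 18 lay lower (median -0.20, adjusted p = 0.00564, and adjusted p = 0.612 with an estimated correlation). The melanin enzyme gene tyrp1b stood at 192 ± 25.0 FPKM in DMSO eyes and 139 ± 30.9 in IPP eyes and the transcription factor gene tfec at 7.26 ± 0.570 and 5.2 ± 1.1. Of 23 genes of the visual cycle and retinoid handling, 6 of which are shared with the list before, 17 lay lower (median -0.20, adjusted p = 0.0262, and adjusted p = 0.584 with an estimated correlation). The visual cycle call ended without DMSO library 2 (adjusted p = 0.07), IPP library 2 (0.0503) or IPP library 3 (0.0714), with the filter at 2 FPKM (0.213) and with the covariates (0.193). The retinaldehyde-binding protein gene rlbp1b stood at 28.4 ± 3.11 and 18.3 ± 4.2 FPKM (-0.64, SE 0.16), with all 4 IPP libraries below all DMSO libraries. Its adjusted p was 0.303 over all genes and 0.028 over the 12 genes that were to be reported in any case. The retinoid isomerase gene rpe65a stood at 399 ± 73.9 and 315 ± 129 FPKM and the retinoic acid hydroxylase gene cyp26a1 at 22.5 ± 8.23 and 14.3 ± 4.40.

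Lipid synthesis genes lay higher in IPP eyes. Of 22 genes of cholesterol synthesis 19 lay higher (median 0.16, adjusted p = 0.00174, and adjusted p = 0.584 with an estimated correlation). Among them were sqlea, the squalene epoxidase, at 3.51 ± 1.01 FPKM in DMSO eyes and 6.53 ± 1.24 in IPP eyes, fdft1, the squalene synthase, at 10.7 ± 2.09 and 16.9 ± 4.34, and ldlra, a low-density lipoprotein receptor, at 4.65 ± 0.154 and 11.4 ± 7.82. Of these genes sqlea alone passed when adjusted over the list alone. The cholesterol list had an exact two-sided permutation p of 0.0286 before and 0.269 after adjustment over the lists. Of 14 genes of fatty acid synthesis and storage 12 lay higher (median 0.18, adjusted p = 0.0347, and adjusted p = 0.584 with an estimated correlation). The regulator gene srebf1 changed by 0.86 on the log2 scale (SE 0.27) and the fatty acid synthase gene fasn stood at 4.51 ± 2.1 and 7.16 ± 0.414 FPKM. The fatty acid call ended without DMSO library 1 (adjusted p = 0.0551), IPP library 1 (0.0859) or IPP library 4 (0.141). Skin genes differed between the same libraries, and liver and gut genes lay high in DMSO library 1 and IPP library 2, at 1.11 and 1.23 above the mean of the eye libraries. With the covariates neither lipid list passed (adjusted p = 0.127 for each). Without DMSO library 4 and IPP library 4 neither passed (0.052 for cholesterol and 0.157 for fatty acids). The fatty acid call also ended with no filter (adjusted p = 0.0838), with library quality weights (0.0555) and without IPP libraries 3 and 4 (0.182).

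Of 42 cell cycle genes 35 lay higher (median 0.12, adjusted p = 0.00423, and adjusted p = 0.612 with an estimated correlation). The topoisomerase gene top2a stood at 23.0 ± 0.995 and 27.7 ± 2.57 FPKM and the ribonucleotide reductase gene rrm1 at 58.0 ± 2.67 and 66.8 ± 3.18. Of 32 genes that neurons induce when active 24 lay higher (median 0.48, adjusted p = 0.0213, and adjusted p = 0.811 with an estimated correlation). The high values were those of IPP libraries 3 and 4. The immediate early gene fosab stood at 535 and 389 FPKM there, at 32.9 and 127 in the other IPP libraries and at 46.9 to 121 in the DMSO libraries. The list call ended without DMSO library 1 (adjusted p = 0.119), DMSO library 4 (0.123), IPP library 3 (0.417) or IPP library 4 (0.315), and without both of those IPP libraries the list lay lower (mean -0.18, adjusted p = 0.0537). Among its members, egr3 changed by 1.31, fosaa by 1.05 and nr4a2a by -0.61 on the log2 scale. Of 23 innate immune genes 16 lay higher (median 0.24, adjusted p = 0.0476, and adjusted p = 0.786 with an estimated correlation). The adaptor gene myd88 stood at 3.64 ± 0.946 and 8.49 ± 4.09 FPKM and the cytokine signalling inhibitor socs3b at 9.91 ± 1.75 and 69.2 ± 63.0. That call ended without any 1 of DMSO libraries 1, 2 and 4 and IPP libraries 3 and 4 (adjusted p 0.0679 to 0.712), and without both of the latter the list lay lower (mean -0.03).

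Markers of tissue around the retina also differed between the groups. Of 36 skin genes 31 lay higher in IPP eyes (median 0.29, adjusted p = 0.000335, and adjusted p = 0.612 with an estimated correlation). The keratin gene krtt1c19e stood at 342 ± 91.9 and 482 ± 52.8 FPKM and the cadherin gene cdh1 at 6.42 ± 1.26 and 10.2 ± 3.79. The skin level of DMSO libraries 1 and 2 lay at -0.50 and -0.43 on the log2 scale relative to the mean of the eye libraries, against -0.08 to 0.46 in the other 6 libraries. Cartilage and connective tissue genes lay higher in 36 of 42 cases (median 0.16, adjusted p = 0.0213, and adjusted p = 0.811 with an estimated correlation). This call ended without DMSO library 1 (adjusted p = 0.375), DMSO library 2 (0.209) or IPP library 4 (0.474). Blood cell genes lay higher in 15 of 21 cases (median 0.26, adjusted p = 0.0199, and adjusted p = 0.584 with an estimated correlation). The globin gene hbae1.3 stood at 11 ± 3.12 and 19.6 ± 5.42 FPKM, and the call ended without DMSO library 2 (adjusted p = 0.0746) or IPP library 4 (0.0703). Skeletal muscle genes lay lower in 23 of 29 cases (median -0.30, adjusted p = 0.0125, and adjusted p = 0.786 with an estimated correlation). It ended without DMSO library 4, whose muscle level lay 0.98 above the mean of the eye libraries (adjusted p = 0.725), or IPP library 3 (0.176). Lens genes, which took 10.2% to 14.6% of the reads of an eye library, lay lower in 42 of 56 cases (median -0.13, adjusted p = 0.0286, and adjusted p = 0.811 with an estimated correlation). The lens call ended without any 1 of DMSO libraries 1 and 3 and IPP libraries 1 and 2 (adjusted p 0.0861 to 0.523) and with quantile normalization (0.247).

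Among single eye genes, the 5 with the smallest p-values in each direction that met the naming rule are given here. The lowest p belonged to irx4a (ENSDARG00000035648, chromosome 16, 378766 to 383664), at 23.8 ± 2.84 FPKM in DMSO eyes and 12.6 ± 1.33 in IPP eyes (log2 fold change -0.89, SE 0.12, adjusted p = 0.189). The AMPA receptor auxiliary gene cacng5a (ENSDARG00000003326, chromosome 6, 21395051 to 21455822) stood at 22.0 ± 0.865 and 14.5 ± 0.351 FPKM (-0.58, SE 0.08). The calcium sensor gene vsnl1a (ENSDARG00000023228, chromosome 20, 35382482 to 35429737) stood at 54.1 ± 5.39 and 30.4 ± 4.07 (-0.82, SE 0.12). The stathmin gene stmn4 (ENSDARG00000030106, chromosome 20, 34773646 to 34868814), a regulator of microtubules that overlaps 3 genes of the opposite strand, stood at 36.6 ± 3.47 and 20.1 ± 3.47 (-0.86, SE 0.13). The ganglion cell gene isl2b (ENSDARG00000053499, chromosome 7, 29992889 to 29997444) stood at 53.6 ± 8.51 and 30.5 ± 3.04 (-0.80, SE 0.12). Each of these 5 genes had an adjusted p of 0.189 and lay lower in all 4 IPP libraries than in any DMSO library.

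The higher ones were apoa4b.2 (ENSDARG00000020866, chromosome 16, 23947196 to 23948538), an apolipoprotein gene, at 0.525 ± 0.297 and 5.71 ± 4.51 FPKM (log2 fold change 2.38, SE 0.45), and pptc7b (ENSDARG00000052658, chromosome 10, 8437930 to 8468949), a phosphatase gene, at 7.50 ± 2.44 and 15.9 ± 1.61 (1.08, SE 0.20). With them were macf1b (ENSDARG00000089435, chromosome 16, 5579744 to 5582764), a cytoskeletal crosslinker gene, at 0.397 ± 0.449 and 1.98 ± 0.254 (1.57, SE 0.30), and pmepa1 (ENSDARG00000039325, chromosome 6, 60076456 to 60104628), an inhibitor of TGF-beta signalling, at 1.96 ± 0.731 and 5.64 ± 1.71 (1.32, SE 0.26). The last was pitpnb (ENSDARG00000036005, chromosome 10, 4046448 to 4085216), a phosphatidylinositol transfer protein gene, at 7.27 ± 0.625 and 10.6 ± 0.638 (0.52, SE 0.10). Their adjusted p-values ranged from 0.24 to 0.274, and all 4 IPP libraries lay above all DMSO libraries in each. Of the other genes to be reported in any case, the acetylcholinesterase gene ache changed by -0.37 (SE 0.12; adjusted p = 0.0784 over the 12 genes), the aryl hydrocarbon receptor target cyp1a by -0.30 (SE 0.29), the glial gene gfap by -0.05 (SE 0.19) and the myelin gene mbpa by 0.16 (SE 0.25).

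**Figure D2:**
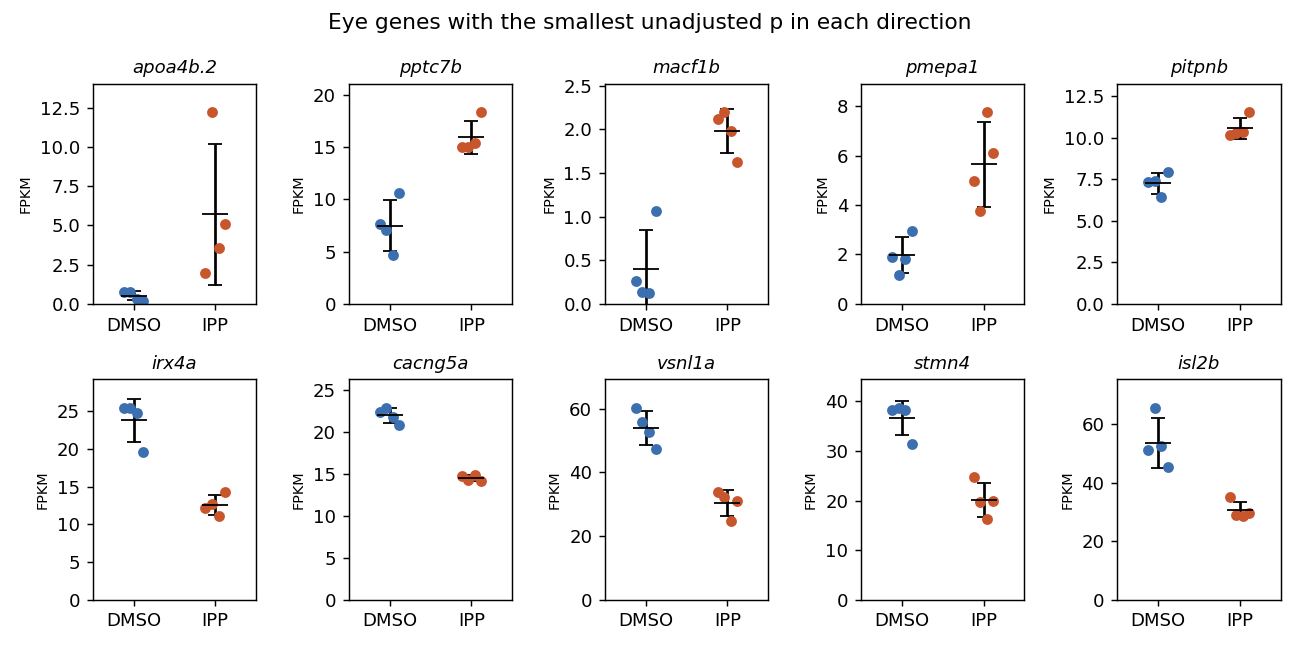
FPKM of the 5 genes per direction with the smallest unadjusted p in eye, in DMSO and IPP eyes, on y axes that start at 0; dots are libraries and black bars the mean with 1 SD (4 libraries per group). In each gene the 4 IPP libraries lie on 1 side of all DMSO libraries, as in irx4a, with a mean of 23.8 in DMSO eyes and 12.6 in IPP eyes.

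By limma, 0 of 17096 genes passed in eye (smallest adjusted p 0.189), with 0 by limma-voom on the rebuilt reads (0.182). At an unadjusted p under 0.05 lay 1886 genes, 906 higher and 980 lower, where chance gives 855. In 380 genes all IPP libraries lay above all DMSO libraries and in 605 all lay below, 5.76% of the genes tested against 2.86% by chance. DMSO library 4 stood with the IPP libraries on the first principal component (17.2, against 15.8 to 23.3 for IPP and -39.4 to -20.7 for the other DMSO libraries). Without it 2935 genes lay at an unadjusted p under 0.05 and 3 passed, irx4a and, higher, macf1b and LO017802.1, the last named after its values were seen. Without DMSO library 2 there were 1242 such genes and 0 passed. Without IPP library 1 a single gene passed, the microRNA gene dre-mir-146a, also named after its values were seen. Over all 4 libraries of a group, IPP library 1 included, its mean was 0 FPKM in DMSO and 4.09 in IPP eyes. For so short a gene that is few reads. DMSO library 4 and IPP library 4 were the highest in muscle and in skin genes. Without both, 40 genes passed by limma, 8 lower and 32 higher. This alternative was chosen after seeing the data, and it leaves out the DMSO library that stood with the IPP libraries. The adjusted p was 0.0365 for irx4a and 0.0482 for tyrp1b, pou4f1 and macf1b. At an unadjusted p under 0.05 there were then 3175 genes. With the levels of the skin list and of the liver and gut list as covariates there were 683, fewer than chance gives, and 0 passed. The keratin gene krt91 of the skin list stood at 506 to 770 FPKM in the eye libraries, and most skin genes lay higher in IPP eyes. The skin level thus need not measure tissue from outside the eye, and as a covariate it may take away an effect of the treatment. A call that ended with the covariates is not shown to come from foreign tissue.

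Of the 47 lists, 18 passed in eye with the preset correlation, 8 higher and 10 lower (12 higher and 9 lower of 21 with quantile normalization). With the estimated correlation 0 passed, and by limma's fry, which tests whether the genes of a list move on balance in 1 direction, 0 passed (smallest adjusted p 0.147), while its test for changes in either direction passed 11. By the exact permutation test 0 lists passed (smallest adjusted p 0.269). With a smallest possible p of 0.0286, a fully separated list passes the adjustment only if most of the 47 lists reach that p. This test could thus hardly pass any list, and its 0 does not show that no list differed. Of the 18 called lists 2 had an unadjusted permutation p under 0.05, those of horizontal and amacrine cells and of cholesterol synthesis. A list that was not called, that of fatty acid oxidation and PPAR targets, had the same p of 0.0286. In the other 16 called lists it ran from 0.0571 to 0.743, with 0.229 for skin, 0.314 for activity-induced genes, 0.457 for lens, 0.486 for muscle and 0.514 for cartilage. Without DMSO library 4 and IPP library 4, 10 lists passed, 8 lower and 2 higher. With the covariates 11 passed, and the calls of blood cells (adjusted p = 0.506), cartilage (0.193), activity-induced genes (0.304), lens (0.413) and immune genes (0.928) were among those that ended. With no filter the blood and cartilage calls ended (adjusted p = 0.0689 and 0.0838), with the filter at 2 FPKM the lens call (0.0737), and with library quality weights the activity-induced and immune calls (0.207 for each). The immune call also ended with a pseudocount of 0.1, the filter at 2 FPKM, quantile normalization, limma-voom and rescaling without lens genes (adjusted p 0.051 to 0.0735).

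The comparison of IPP brains with DMSO brains asks what the exposure did in the organ that processes the light signal. Of the lists called here with the preset correlation, all but that of blood cells lost the call when 1 of the libraries was left out. With an estimated correlation 0 lists passed. Genes of ribosomal proteins lay higher in IPP brains in 67 of 73 cases (median 0.11), nuclear genes of oxidative phosphorylation in 59 of 69 (median 0.11) and blood cell genes in 16 of 20 (median 0.37). Genes of mature neurons lay lower in 30 of 33 cases (median -0.10). No single gene passed the correction. The inner-retina lists that lay lower in IPP eyes were not called by camera in brain. The ganglion cell list had a median of -0.07 (adjusted p = 0.138), with 16 genes lower and 9 higher. The horizontal and amacrine cell list had a median of -0.02 (adjusted p = 0.31), with 16 lower and 12 higher. The lists were not tested for a difference between the tissues, so this does not show a change in eye alone.

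The brain libraries differed in genes typical of tissue outside the brain. DMSO library 1 and IPP library 4 were high in liver and gut genes, with the liver gene apoa2 at 2186 and 3822 FPKM against 1.25 to 8.10 in the other 6 libraries. Skin genes lay high in DMSO library 4, IPP library 3 and IPP library 4, at 1.78, 1.88 and 2.09 above the mean of the brain libraries on the log2 scale, against -1.92 to 0.11 in the other 5. The cartilage gene col2a1a stood at 83.4 to 129 FPKM in DMSO libraries 3 and 4 and IPP libraries 3 and 4 and at 3.26 to 4.64 in the others. IPP library 4 stood apart from all others on the first principal component (-113, against -17.0 to 42.5).

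**Figure D3:**
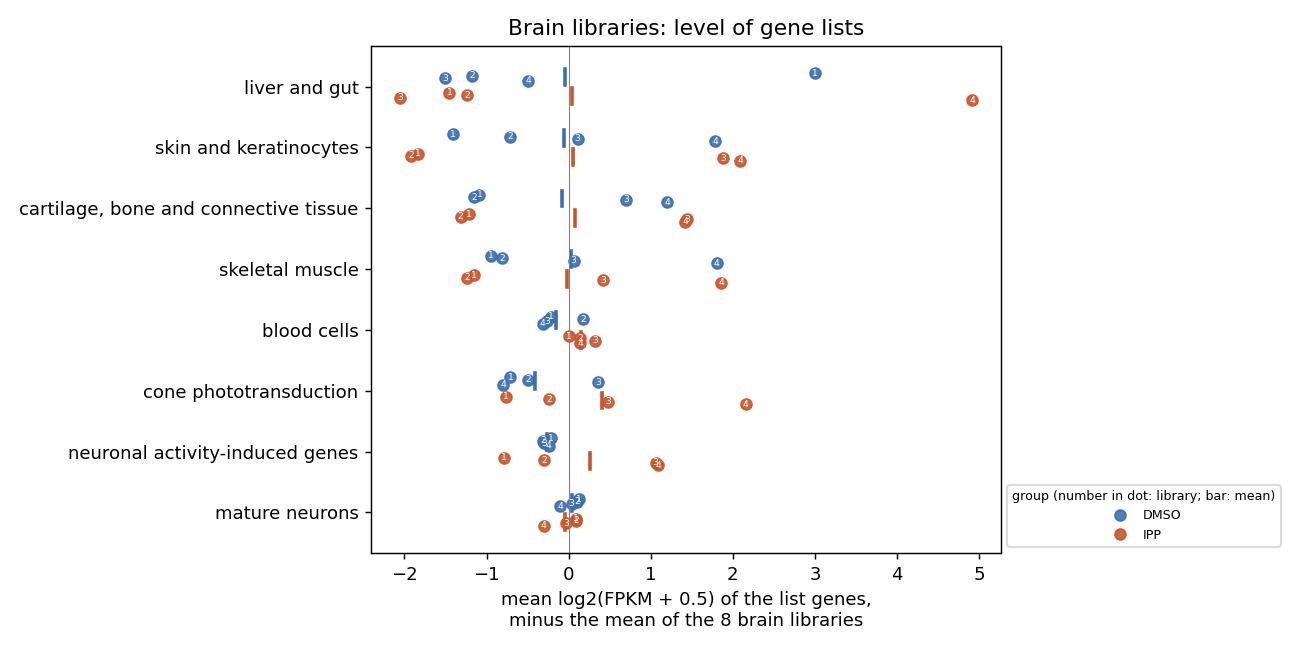
Mean log2(FPKM + 0.5) of the genes of 8 fixed lists in each brain library, minus the mean of the 8 brain libraries, on the x axis, with 1 list per line; dots are libraries with their number, blue for DMSO and orange for IPP, and bars are group means. DMSO library 1 and IPP library 4 stand at 3 and 4.92 in the liver and gut list, and IPP libraries 3 and 4 at 1.06 and 1.09 in the list of activity-induced genes.

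The ribosomal list (adjusted p = 4.0e-05, and adjusted p = 0.973 with an estimated correlation) included rps27a at 58.3 ± 7.89 FPKM in DMSO brains and 79.9 ± 13.9 in IPP brains and rps12 at 44.1 ± 5.67 and 54.3 ± 5.88. Its call ended without DMSO library 3 (adjusted p = 0.0561) or IPP library 4 (0.359). The oxidative phosphorylation list (adjusted p = 4.0e-05, and adjusted p = 0.973 with an estimated correlation) included the ATP synthase gene atp5mc3a at 69.9 ± 4.90 and 81.4 ± 2.18, while the succinate dehydrogenase gene sdhda lay lower, at 3.35 ± 0.622 and 2.08 ± 0.292. Its call ended without DMSO library 3 (adjusted p = 0.0525). The blood cell list (adjusted p = 0.000717, and adjusted p = 0.973 with an estimated correlation) included the red cell anion exchanger gene slc4a1a at 3.63 ± 1.19 and 6.27 ± 1.08 and hbae1.3 at 9.59 ± 1.52 and 13.2 ± 1.59. No single library ended the blood call, which ended without IPP libraries 3 and 4 together (adjusted p = 0.0682). The mature neuron list (adjusted p = 0.00263, and adjusted p = 0.973 with an estimated correlation) held the kinase gene camk2b1 at 95.3 ± 3.34 and 85.5 ± 6.05, while uchl1 lay higher, at 30.9 ± 1.59 and 35.5 ± 2.4. Its call ended without DMSO library 1 (adjusted p = 0.0573), DMSO library 2 (0.0542) or IPP library 4 (0.832). The glutamate signalling list lay lower in 28 of 40 genes (median -0.06, adjusted p = 0.0301, and adjusted p = 0.973 with an estimated correlation). Its receptor gene grm5a stood at 12.5 ± 0.554 and 10.1 ± 0.911, and the call ended without any 1 of DMSO libraries 1 and 3 and IPP libraries 3 and 4 (adjusted p 0.0993 to 0.63).

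Activity-induced genes lay higher in 28 of 32 cases (median 0.47, adjusted p = 7.4e-05, and adjusted p = 0.973 with an estimated correlation). The immediate early gene jun stood at 48.8 ± 2.4 and 98.2 ± 54.9 FPKM and fosaa at 32.1 ± 3.17 and 76.9 ± 65.1. As in eye, the high values were those of IPP libraries 3 and 4, where the activity-dependent gene npas4a stood at 515 and 284 FPKM, against 44.5 and 110 in IPP libraries 1 and 2 and 117 to 202 in the DMSO libraries. The call ended without IPP library 3 (adjusted p = 0.148), and without both libraries the list lay lower (mean -0.28, adjusted p = 0.000361). Cone phototransduction genes lay higher in 16 of 17 cases (median 0.79, adjusted p = 0.00073, and adjusted p = 0.973 with an estimated correlation). The cone transducin gene gngt2b stood at 1.94 ± 1.57 and 12.6 ± 13.9 FPKM. The cone call ended without IPP library 4 (adjusted p = 0.452), in which the ultraviolet cone opsin gene opn1sw1 stood at 64.9 FPKM against 0.229 to 12.5 in the other brain libraries. The opsin genes rho, opn1mw1 and opn1lw2 changed by 1.02 (SE 1.18), 1.55 (SE 1.03) and 1.61 (SE 0.85) in brain.

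The remaining list calls in brain were higher ones of the p53 response (22 of 27 genes, median 0.25, adjusted p = 0.00165), xenobiotic metabolism (28 of 32, median 0.41, adjusted p = 0.00872), heat shock (19 of 26, median 0.16, adjusted p = 0.0107), the innate immune response (18 of 25, median 0.24, adjusted p = 0.0155) and the circadian clock (26 of 33, median 0.21, adjusted p = 0.0226). For each of them the adjusted p = 0.973 with an estimated correlation. Each ended without IPP library 4 (adjusted p = 0.167 for p53, 0.281 for heat shock, 0.676 for immune and 0.887 for clock genes), and the xenobiotic list was then called lower (mean -0.27, adjusted p = 0.0469). All but the xenobiotic list also ended without IPP library 3 (adjusted p 0.0587 to 0.0976). In addition, the xenobiotic and immune calls ended without DMSO library 3 (adjusted p = 0.0638 and 0.0525), the heat shock call without DMSO library 1 (0.0573), and the clock call without any 1 of DMSO libraries 1, 2 and 3 (0.0525 to 0.11). The glutathione transferase gene gstm.1 stood at 45.8 ± 3.72 and 57.0 ± 4.97 FPKM and the heat shock gene hsp70.3 at 0.374 ± 0.120 and 6.01 ± 7.98. The gene cyp1a stood at 9.37 FPKM in DMSO library 1 and 35.5 in IPP library 4, the libraries high in liver and gut genes, and at 0.218 to 1.1 in the other 6 (log2 fold change 0.54, SE 1.29).

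The brain gene with the smallest p was smtlb (ENSDARG00000017251, chromosome 10, 39314578 to 39321367), the gene of the pituitary hormone somatolactin beta, at 6.73 ± 1.82 FPKM in DMSO brains and 1.12 ± 0.914 in IPP brains (log2 fold change -2.26, SE 0.37). It was followed by the transcription factor gene foxd2 (ENSDARG00000058133, chromosome 8, 19674369 to 19676640), at 10.5 ± 0.946 and 6.85 ± 0.465 (-0.58, SE 0.10), and by mlf2, at 8.16 ± 0.929 and 5.44 ± 0.389. The homeobox genes shox and pou4f2 (ENSDARG00000069737, chromosome 1, 36436936 to 36440301) stood at 131 ± 6.83 and 94.1 ± 14.1 and at 76.0 ± 6.05 and 53.7 ± 8.88 FPKM. Higher were the sorting nexin gene snx6 (ENSDARG00000058444, chromosome 17, 9963436 to 10000339), at 6.60 ± 0.785 and 9.57 ± 1.16 (0.50, SE 0.12), and atrxl (0.58), sub1b (0.72), abhd17aa (0.66) and slc7a4 (0.77). In each of these 10 genes all IPP libraries lay on 1 side of all DMSO libraries, and each had an adjusted p of 1. Of the other genes to be reported in any case, rpe65a stood at 1.45 ± 0.350 and 2.61 ± 0.642 FPKM (adjusted p = 0.125 over the genes of that set tested in brain), and ache, gfap, mbpa, gnat1 and gnat2 changed by -0.11, -0.14, -0.29, 0.01 and 0.91 on the log2 scale. The genes cyp26a1 and rlbp1b lay below the filter in brain and were not tested there.

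By limma, 0 of 17533 genes passed in brain (smallest adjusted p 1), with 0 by limma-voom. At an unadjusted p under 0.05 lay 512 genes, 273 higher and 239 lower, where chance gives 877. There were 769 without IPP library 1, and 1437 with the levels of the skin list and of the liver and gut list as covariates, where 0 passed as well. The groups were fully separated in 2.06% of the genes, against 2.86% by chance. On simulated data with the spread of these libraries the same test found 55 of 100 brain genes and 73 of 100 eye genes changed by 2-fold, and 85 and 96 of 100 changed by 4-fold. These rates are for genes with a mean of at least 2 FPKM that vary independently, and may not hold for libraries that shift in many genes together. Of the 47 lists, 12 passed in brain with the preset correlation, 10 higher and 2 lower, 0 with an estimated correlation, 0 by fry (smallest adjusted p 0.98) and 0 by the exact permutation test (smallest adjusted p 0.971). Without DMSO library 3, and likewise without IPP library 3, 6 lists passed, and without DMSO library 4, and likewise without IPP library 1, 18 passed. With library quality weights the calls of oxidative phosphorylation and blood cells alone of those 12 stayed past the threshold, and with no filter the glutamate call ended (adjusted p = 0.0581). Without DMSO library 1 and IPP library 4 together, an alternative chosen after seeing the data, 0 genes passed (smallest adjusted p 0.0703) and 8 lists did, 4 higher and 4 lower.

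The comparison of the effects in both tissues asks whether IPP acted alike in eye and brain. It spans tables that the authors normalized separately, and each effect was taken within its own table. Across the 15856 genes tested in both tissues, the log2 fold changes had a Pearson r of 0.295 (jackknife SE 0.201 over the 16 libraries, and 0.201 over the 8 pairs of same-labelled eye and brain libraries) and a Spearman rho of 0.275, where genes are not independent replicates. Without brain DMSO library 2 the r was 0.16, and without DMSO library 2 of both tissues 0.128. At an unadjusted p under 0.05 in both tissues lay 87 genes, where 52.0 would be shared by chance, with 33 higher in both (13.1 by chance) and 44 lower in both (12.8 by chance). These chance counts assume that eye and brain libraries vary independently. By limma's interaction test, 0 genes had a different effect in the tissues (smallest adjusted p 0.972), with 0 by limma-voom (0.795) and 640 genes at an unadjusted p under 0.05, where chance gives 793, or 1145 without eye DMSO library 4. That test takes the libraries as independent. With same-labelled eye and brain libraries paired, chosen after seeing the data, 0 genes passed (smallest adjusted p 0.226) and 1028 lay at an unadjusted p under 0.05. Libraries of the same treatment and number deviated from their group alike in eye and brain in 7 of 8 cases (correlation across genes from -0.14 to 0.44), the highest being DMSO library 4. More sharing than these chance counts can thus arise without an effect of IPP.

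**Figure D4:**
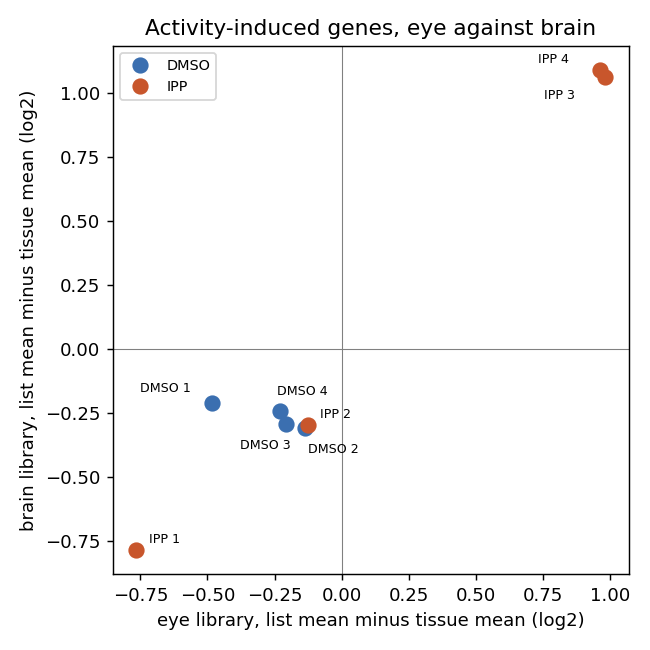
Mean log2(FPKM + 0.5) of the 32 activity-induced genes in each eye library, minus the mean of the 8 eye libraries, on the x axis, against the same value for the brain library of the same treatment and number on the y axis, with DMSO in blue and IPP in orange. IPP libraries 3 and 4 stand at 0.98 and 0.96 in eye and at 1.06 and 1.09 in brain, and IPP library 1 at -0.76 and -0.79.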

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

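The tests of the sources of liver and gut genes given here were chosen after the values were seen. In 278 groups of 4 libraries, the highest or the lowest value was checked against the others by Dixon's criterion, and 21 were marked. Chance marks about 1 in 20 groups, or 13.9 of 278.

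Liver and gut genes and xenobiotic genes were high in single brain libraries. The liver and gut list of brain IPP library 4 lay at 4.92 above the mean of the brain libraries on the log2 scale (other IPP libraries -2.06 to -1.24), and its xenobiotic list lay at 2.24 (other IPP libraries -0.60 to -0.25). The gene cyp1a stood at 35.5 FPKM in that library and at 9.37 in brain DMSO library 1, against 0.218 to 1.1 in the other 6. IPP exposure does not account for the high level of DMSO library 1, which had the vehicle alone. The liver and gut level of 3 of the 4 IPP brain libraries lay at or below the highest DMSO library (exact two-sided permutation p of 0.943). That library is DMSO library 1 itself, so this count restates the pattern and does not test the source in IPP library 4. Tissue from outside the brain, carried along in dissection, is a candidate source and stays open. Of the 39 measured liver and gut genes 35, or 89.7%, were higher in both DMSO library 1 and IPP library 4 than in each of the other 6 libraries. This count describes the pattern and does not test where the RNA came from, since the same list singled out these libraries. The liver gene apoa2 stood there at 2186 and 3822 FPKM and the pancreas gene prss1 at 224 and 3435, and 17 of the 39 genes reach 1 FPKM in the mean of the other 6. Liver RNA may be a source of the cyp1a and xenobiotic values of these libraries as well, but the xenobiotic list shares 0 genes with the liver and gut list and its genes were not tested for their source.

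In eye, the share of mitochondrial reads was high in DMSO library 3 (4.41%, others 3.94% to 3.98%) and in IPP library 3 (4.32%, others 4.12% to 4.14%). DMSO library 4 was the highest DMSO library for macf1b (1.06 FPKM, others 0.128 to 0.265) and gfap (2.91, others 2.39 to 2.47) and the lowest for irx4a (19.5, others 24.8 to 25.4) and stmn4 (31.4, others 38.2 to 38.6). IPP library 4 was the highest IPP library for pptc7b (18.3 FPKM, others 15.0 to 15.4), pitpnb (11.5, others 10.1 to 10.4), rho (4959, others 4165 to 4243) and ldlra (23.0, others 6.53 to 8.88). DMSO library 2 was low for opn1mw1 (2674 FPKM, others 2823 to 2827), and IPP library 3 was low for gria4a (10.9, others 14.1 to 14.4). The gene sv2ba was low in DMSO library 3 (33.0 FPKM, others 39.6 to 40.8), as was the list of synaptic vesicles and release (-0.16, others 0.07 to 0.08), and sv2ba was high in IPP library 1 (58.4, others 48.0 to 48.7). The gene apoa1a was high in DMSO library 1 (17.5 FPKM, others 0.857 to 3.64). In brain, gnat1 was high in DMSO library 3 (2.95 FPKM, others 0.317 to 0.745).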

How the results depend on the processing

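Protein-coding genes only, the sets of 2 left-out libraries, the covariates and the pairing of same-labelled eye and brain libraries were tests chosen after the results were seen. The count of genes that passed stayed 0 in brain in the alternatives run and with each library left out. For the interaction it stayed 0 as well, where rescaling without lens genes, the left-out pairs of eye DMSO 4 and IPP 4 and of brain DMSO 1 and IPP 4, and the covariates were not run. In eye it was 0 to 3 with 1 library left out and 0 in all other alternatives but 1. Median-of-ratios scaling moves nothing by its construction, since the FPKM already hold it. A block by replicate number left 0 genes in each comparison, 18 lists in eye and 15 in brain. In eye the numbers do not pair samples (correlation of same-numbered libraries -0.09 to 0.04, each below the highest with another number). In brain, numbers 2 and 3 correlated at 0.33 and 0.20, above the highest with another number (0.24 and 0.18). Brain numbers 1 and 4 did not (-0.09 and 0.07, against 0.38 and 0.39 with another number). Something shared by number is thus not excluded in brain. No scaling moved the median fold change of all genes by as much as 0.05. Of the values of single genes named in the text, 712 with 1 library left out and 1309 in other alternatives kept direction and side of the threshold, 22 and 28 changed sign and 2 and 4 newly passed. Of those of lists, 243 and 497 kept both, 57 and 120 no longer passed, 6 and 9 newly passed and 6 and 23 turned. With 1 library left out 13 to 21 lists passed in eye and 6 to 18 in brain, and r between tissues was 0.16 to 0.355.

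The values that moved follow, as counts, log2 fold changes or list means, and the cause was not tested. With an estimated correlation or by fry, 0 lists passed in eye and 0 in brain. Without eye DMSO 4 and IPP 4, 40 genes and 10 lists passed in eye, and gnat1 was -0.0788, gfap 0.12 and the GABA and glycine list 0.0857. With the covariates 11 lists passed in eye, and rho was 0.11, gnat2 0.0474, mbpa -0.31, the cartilage list -0.18, the bipolar cell list -0.00205 and the rod list 0.0889 in eye and gnat1 -0.0224 in brain. With a pseudocount of 0.1 gnat1 was -0.0246 in brain. With quantile normalization rho was 0.0555, gnat2 0.0407, the rod list 0.0326 and the Mueller glia list 0.00700 in eye. With library quality weights gnat1 was -0.0231 and gfap 0.0238 in eye, and in brain cyp1a was -0.53, rho -0.34, gnat1 -0.51, ache 0.0229, gfap 0.0690 and the xenobiotic list -0.0861. Without brain DMSO 1 and IPP 4, rho was -0.0700, gnat1 -0.43, ache 0.0241, the mature neuron list 0.0375 and the xenobiotic list -0.0728. Without IPP 3 and IPP 4, gnat1 was -0.0792, gfap 0.24, the activity list -0.18, the GABA and glycine list 0.0853 and the immune list -0.0271 in eye. In brain, cyp1a was then -0.90, rho -0.81, opn1mw1 -0.0132, gnat1 -0.80, gnat2 -0.23, ache 0.16 and gfap 0.33. The brain list means were then ribosomal -0.0443, activity -0.28, cone -0.0939, rod -0.26, p53 -0.0315, mature neurons 0.0495, xenobiotic -0.38, heat shock -0.0294, immune -0.25, clock -0.0802 and glutamate 0.0461. List means also turned sign where the camera direction stayed. The synaptic vesicle list in eye (-0.0284) went to 0.000106 with a pseudocount of 0.1 and 0.0132 by limma-voom. It went to 0.0138, 0.0344 and 0.0192 without DMSO 4 and IPP 4, without IPP 3 and IPP 4 and with the covariates. The rod list in brain (0.28) went to -0.10 with library quality weights and -0.0410 without DMSO 1 and IPP 4. The rod, Mueller glia and GABA and glycine means in eye, at 0.0110, 0.0150 and 0.00460, turned in several alternatives.

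With 1 library left out, the genes that changed sign ranged in eye from -0.0755 to 0.0900 for gnat1, -0.20 to 0.0424 for rho, -0.12 to 0.15 for opn1mw1, -0.0717 to 0.23 for opn1lw2, -0.0669 to 0.00652 for gnat2, -0.19 to 0.0665 for gfap and -0.0156 to 0.32 for mbpa, and the lists from -0.0426 to 0.0588 for rods, -0.0248 to 0.0576 for Mueller glia and -0.0680 to 0.0769 for GABA and glycine. In brain they ranged from -0.34 to 0.46 for gnat1, -0.37 to 0.0936 for gfap, -0.72 to 1.35 for cyp1a and -0.19 to 0.0229 for ache, and the xenobiotic list from -0.27 to 0.68. Without IPP 4 the brain means of mature neurons and immune genes turned to 0.00920 and -0.0162.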

Other observations

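Of the tests given here, that of brain tissue carried over into eyes and the splits for unadjusted p, lists, interaction and correlation were set before their results were seen, and all others were chosen after them. Beside apoa4b.2, 2 further apolipoprotein genes, named after their values were seen, had higher means in IPP eyes and did not pass. The gene apobb.1 stood at 0.178 ± 0.151 FPKM in DMSO eyes and 2.81 ± 2.01 in IPP eyes (log2 fold change 2.08, SE 0.43, adjusted p = 0.274). The gene apoa1a stood at 6.13 ± 7.65 and 46.7 ± 37.7 (2.99, SE 0.86, adjusted p = 0.333), with IPP library 1 (8.33) below DMSO library 1 (17.5). In apoa2, DMSO library 1 (60.4 FPKM) lay above 3 of the 4 IPP libraries (12.1 to 35.1). No list of apolipoprotein genes was fixed or tested. The genes apobb.1, apoa1a and apoa2 belong to the liver and gut list, of which 17 of 24 measured genes lay higher (median 0.25, adjusted p = 0.0976, and adjusted p = 0.836 with an estimated correlation) and apobb.1 alone passed when adjusted over the list alone. The list passed without DMSO library 1 (adjusted p = 9.8e-06), without IPP library 1 (0.00705), by limma-voom (0.0351) and without IPP libraries 3 and 4 (0.045). Its level was highest in DMSO library 1 and IPP library 2, at 1.11 and 1.23 above the mean of the eye libraries on the log2 scale, against -0.83 to 0.08 in the other 6. With fewer eye libraries, without DMSO 4 and IPP 4, the 8 lower genes that passed included the transcription factor genes pou4f1 (log2 fold change -0.99), pou4f2 (-0.84), irx4a (-1.04) and six3a (-0.83) and the melanin enzyme gene tyrp1b (-0.72), of which pou4f2 and six3a are named after their values were seen.

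The lower level of 53 ganglion, horizontal and amacrine cell genes in IPP eyes (median -0.26, SE 0.06, 43 lower and 10 higher) was weighed against 3 explanations. Brain tissue carried over into DMSO eyes would lower genes abundant in brain and nearly absent from eye by as much. The median log2 ratio of IPP to DMSO eyes of 289 such genes was 0.15 (SE 0.09), where the cell genes had -0.27 (SE 0.06). That set was chosen by the brain mean, which the liver and gut genes of a pair of brain libraries raise. Chosen by the brain median, 191 genes had 0.05 (SE 0.10), which also lies above -0.27, though by less than 2 standard errors of each set added up. Dilution of the retina by skin, cartilage or muscle RNA as the whole cause would lower photoreceptor genes by as much. The median of 73 of them was 0.05 and lay 0.32 above that of the cell genes. The SE of these medians is taken over genes, which vary together in the same eye libraries, and does not measure the spread between libraries. The medians thus go against both explanations as the whole cause but do not exclude them. IPP exposure and chance both stay open. These genes come from 2 lists picked after seeing that they were among the lowest in IPP eyes, so their pooled mean does not test the difference. Taken alone, the ganglion cell list overlaps between the groups (exact two-sided permutation p 0.0571). The list of horizontal and amacrine cells had a permutation p of 0.0286, the smallest possible, and of 0.269 after adjustment over the 47 lists. The adjusted p could pass only if most lists reached 0.0286, so it says little for or against IPP exposure. The splits of the libraries do not exclude chance for the count of lists. Fewer or less mature inner retinal neurons, or lower expression in the same cells, may underlie such a difference and were not told apart.

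Activity-induced genes were high in IPP libraries 3 and 4 of both tissues. The IPP samples did not all lie above the DMSO samples. Of the 8 IPP libraries 3 lay at or below the highest DMSO library of their tissue, 1 of them in eye. IPP libraries 3 and 4 were picked as the high ones, so this count restates the pattern and does not test IPP exposure. An effect of IPP in part of the samples, or a smaller one in all of them, stays open. Skin and connective tissue RNA as the whole cause stays open. A line through the other 6 libraries of each tissue, on their level of skin genes or of cartilage and connective tissue genes, had slopes of -0.0862 to 0.0657. IPP libraries 3 and 4 lay above the level it predicts by 1.25 to 1.34, or 3.56 to 4.46 prediction standard errors. The two-sided bound at 0.05 is 2.78 with 4 degrees of freedom, but it does not hold for libraries picked as the highest. All of them but eye IPP library 3 also lay above the fitted range, so the line does not decide the question. Eye IPP library 3 had a lower skin level than eye DMSO library 4 (0.07 against 0.28). In that library alone, this goes against skin RNA as the whole cause. With the levels of the skin list and of the liver and gut list as covariates, the mean of the activity-induced list went from 0.53 to 0.49 in brain, where it passed (adjusted p = 1.6e-05), and to 0.32 in eye, where the call ended (adjusted p = 0.304). A candidate explanation is handling or harvest shared by eye and brain samples of the same treatment and number. Over the 15824 tested genes outside the list, deviations from the group mean had a mean correlation of 0.22 between same-labelled eye and brain libraries (exact one-sided permutation p 0.00868 over 576 matchings). This shows that eye and brain samples of the same treatment and number share something, not that it raised the activity-induced genes. It does not bear on samples that share a number across treatments. Within the list, 4 of the 8 eye libraries correlated better with a brain library of another label. The labels do not say whether eye and brain of the same treatment and number come from the same larvae, so an effect of the larvae themselves stays open.

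Other splits of the libraries asked whether a grouping by chance gives results as large. In eye, 3 of the 35 splits, the real one included, gave at least as many genes at an unadjusted p under 0.05 as the real 1886. The others, with 1949 and 2775 genes, differ from the treatment only by DMSO library 4 exchanged for IPP library 3 or IPP library 4. At least the real 18 lists were called in 6 of 35 splits, the real one included. The highest other count, 24, came with DMSO library 3 exchanged for IPP library 2. Chance cannot be excluded for either count. In brain, 21 of 35 splits gave at least 512 genes (highest other 2312) and 24 of 35 at least 12 lists (highest other 32), and chance cannot be excluded. The brain split with the highest count at an unadjusted p under 0.05, 2312, set libraries 1 and 2 of both treatments against libraries 3 and 4. The split with the highest count of brain genes that passed, 282, set DMSO libraries 1 and 2 and IPP libraries 3 and 4 against the rest. Both were picked by their counts and group the libraries differently. Groupings other than the treatment thus gave more genes than the treatment did, and what underlies them was not tested. A count of 0 genes that passed is reached by each split by definition, so the splits test nothing there. They are 35 of 35 in eye (highest other 3), 35 of 35 in brain and 100 of 100 drawn splits for the interaction (highest other 2), drawn within each tissue without regard to the labels that eye and brain share. For the correlation between tissues, splits made alike in both tissues gave an r of at least 0.295 in 14 of 35 cases (highest other 0.46, median of the others 0.22), so chance cannot be excluded and the r cannot be read as a shared effect of IPP.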
